A study of Drosophila melanogaster with 134 samples.

How the data were processed

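The series measured, by STAP-seq, how strongly candidate core promoters of Drosophila melanogaster fired when 1 chosen protein was brought next to them. A core promoter is the short stretch of DNA around a transcription start site where RNA polymerase assembles. Each candidate was a synthesized 133 bp piece centred on a start site and cloned behind 4 UAS sequences, the binding sites of the yeast protein Gal4. A recruited protein was a transcriptional cofactor, or the activator p65, brought to the UAS array, and GFP was the control that activates nothing. The pool was stated to hold 72000 candidates, and the tables listed 72000 rows, of which 5 were constructs with a name in place of coordinates. The 134 samples fell into 48 groups by their labels, and 130 of the samples had a column in a table. The 4 input samples were not analysed here. No column of a sample outside the series was used.

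The main tables held whole-number counts, deposited by the authors, of unique tags, which are distinct reporter transcripts, per candidate and library. They were raw: the column totals differed from library to library. Per the submitters' processing notes, CASAVA 1.9.1 and Bowtie 0.12.9 were used and the genome build was dm3; their settings, and how reads were collapsed to unique tags, are not given in the sources used here. A second set of tables held a scaled signal, which the authors deposited as spike-in normalized, per the labels. A script recovered how it was made: in the tables of the 3 cell lines each value was the mean over 3 replicates of the unique tags times 1 factor per library, and in the enhancer table the tags of a library times its factor. This held for 100% of the values at a relative tolerance of 0.0001. GFP replicates 4 to 6 of S2 cells had no factor. How the spike-in transcripts were counted is not given in the sources used here.

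Groups were compared on the counts with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest; edgeR 4.0.16 in R 4.3.3), TMM scaling, edgeR's filterByExpr and a Benjamini-Hochberg adjusted p under 0.05. All libraries of a cell line were fitted together, with the recruited protein as the only term, so that they shared 1 estimate of the spread. TMM takes an average over the promoters of a library, trimmed of extremes, as unchanged. The fitted median over promoters can lie far above that average, as it did in OSC, where many promoters had no GFP tag. A promoter called lower was lower relative to that average, and the call does not say that its transcript output fell. For that reason the counts with the library sizes set by the authors' spike-in factors stand beside the TMM counts. Differences between cell lines were tested as an interaction, the effect of a protein over GFP in 1 line minus that in S2, on the promoters that passed the filter over the 3 lines together.

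The promoters could be named only by position. The files give dm3 coordinates and no gene names or sequences, and the gene table at hand belongs to another assembly, so the gene lists and the sequence motif classes chosen before the data were examined could not be applied. The classes used in their place were set after the tables were opened, without the values of any recruited protein. From the separate enhancer libraries, a promoter with at least 100 tags was called zfh1-preferring when its CPM were at least 4-fold higher with the zfh1 enhancer than with the ssp3 enhancer, and ssp3-preferring in the opposite case, with a prior count of 1. The 100 tags were counted over both zfh1 libraries and the ssp3 library together. The other classes were divergent pairs, candidates with another start site on the opposite strand within 500 bp upstream, pointing away, and the candidates on chromosome X, on chromosome 4, on heterochromatic or unplaced sequence and on the mitochondrial genome. The 137 mitochondrial candidates left no promoter to test. Class shifts were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, over 246 class and comparison pairs adjusted together, and again with an estimated correlation and with fry.

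Promoters named in the text were chosen by a rule set before the data were examined: the largest and the smallest log2 fold changes among those past the test, with an average log2 CPM of at least 2 and no overlap between the replicates of both groups. Because no gene names could be given, at most 2 promoters that rose and 2 that fell are printed per comparison. Positions are 1-based on dm3. Where a group had no tag at a promoter, the fold is given as a lower bound against a floor of 3 tags summed over the group, each scaled to CPM. With 1 to 3 tags the ratio of counts is given with its exact 95% interval. Intervals and floors cover counting error only.

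Replicates were compared by a chi-square test over promoters with at least 10 tags. In OSC cells GFP replicates 1 and 2 differed by no more than sampling noise, with a chi-square per degree of freedom of 1.02 over 947 promoters, while the other pairs of that group gave 1.24 and 1.27. They were summed and counted as 1 sample. The design text calls the S2 replicates biological; nothing says how those of the other lines were made, so p-values measure only the spread between these samples, which may be technical.

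Totals of tags scaled by the spike-in factors were compared by exact two-sided permutation tests, which with 3 libraries against 3 cannot give a p below 0.1. The enhancer screens had 1 library each for no enhancer and for ssp3 and 2 for zfh1, so their ratios are descriptions with no test. Correlations of fold changes across promoters were set beside the values from 5 simulated sets of unchanged groups against the same GFP libraries. Scripts were tested on simulated counts with 200 changed promoters, as many up as down, 1 fixed spread and the compared groups fitted alone. The real fits held all libraries of a line, and many proteins shifted most of the pool. The shares below are therefore not the error rates of the calls reported here. For Chro against GFP in S2, over 9734 promoters, 74% of the 4-fold and 26% of the 2-fold increases were recovered, and 2.86% of the calls were false. For Med25 against Chro these shares were 90% and 40%, with 3.94% false. For Chro against GFP they were 50% and 16% in Kc167, over 15614 promoters, and 22% and 2% in OSC, over 28010 promoters, where 14.3% of the few calls were false. Decreases were recovered less often. Of the 4-fold and 2-fold ones, 32% and 4% were recovered for Chro against GFP in S2, and 78% and 36% for Med25 against Chro. For Chro against GFP in Kc167 these shares were 18% and 4%, and in OSC 0% and 0%.

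The alternatives were DESeq2 1.42.0, the spike-in factors, no filter, a filter at an average log2 CPM of 2, a fold threshold, a replicate block, fewer GFP libraries, each replicate left out, and the compared groups fitted alone. Thinning every library to 100000 tags, keeping the OSC GFP libraries apart, and the spike-in factors in the comparison of cell lines were added after the data were seen.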

Results

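Reporter transcripts were counted for 72000 candidate core promoters in 3 Drosophila cell lines. S2 and Kc167 cells are embryonic lines with properties of blood cells, and OSC cells are somatic cells of the ovary. In S2 cells 23 cofactors and p65 were each recruited in 3 libraries, with 6 libraries of the GFP control. In OSC and in Kc167 cells 7 of these proteins and GFP were recruited in 3 libraries each. In 4 more S2 libraries the recruitment sites gave way to no enhancer, to an enhancer of the gene zfh1 or to an enhancer of ssp3. Depth followed the recruited protein: the 78 S2 libraries held 12837 to 4903278 unique tags, with a median of 155672, the 24 OSC libraries 16359 to 4493869 and the 24 Kc167 libraries 41109 to 3215829. The GFP libraries were among the shallowest, with 12837 to 80569 tags in S2, where the Tbp libraries held 23612 to 72814, 16359 to 45766 in OSC and 41109 to 108839 in Kc167, so the depth of GFP limits most comparisons. The 4 enhancer libraries held 119017 to 2820163 tags.

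The first comparison asked how strongly each protein activated the promoter pool as a whole. In S2 cells p65, the activating subunit of mammalian NF-kappaB, raised the total of spike-in scaled tags 120-fold over GFP, Nej_p300, the fly homologue of the acetyltransferases CBP and p300, 117-fold, and the Mediator subunit Med25 95.02-fold. Lpt, a partner of the histone methyltransferase trr, raised it 48.6-fold and Med15, another Mediator subunit, 27.5-fold. The DNA-associated proteins gfzf, pzg and Chro followed at 18.6-fold, 15.2-fold and 13.3-fold, and the histone H4 acetyltransferase Mof at 9.72-fold. The least active were Tbp, the TATA-binding protein, at 1.48-fold, Gcn5_pCAF at 1.30-fold and Atac2 at 1.26-fold. On the log2 scale these ranged from 6.92 ± 0.16 for p65 to 0.34 ± 0.15 for Atac2 (SE, n = 3 libraries each). For 22 of the 24 proteins every library lay above every GFP library, which gives an exact permutation p of 0.1, the smallest that 3 against 3 allows; for Gcn5_pCAF and Atac2 the exact permutation p was 0.2. A total over 2-fold was reached by 20 of the 24 proteins, and by 23 when raw tags were used. In OSC cells the order changed in 1 place of note: p65 reached 119-fold and Med25 52.4-fold, but Nej_p300 6.23-fold, below Lpt at 12.1-fold, gfzf at 9.17-fold and Chro at 7.22-fold. With raw tags Nej_p300 stood at 27.7-fold in OSC, below Lpt at 49.3-fold but above gfzf at 21.04-fold and Chro at 17.8-fold. In Kc167 cells Med25 reached 25.6-fold, p65 22.8-fold and Nej_p300 19.1-fold, with a log2 SE of 0.84 to 1.02. There replicate 2 had the highest spike-in scaled total not only with GFP, at 89811 against 19271 and 15254, but also with Med25, p65, Chro, Mof and gfzf, and the SE and the exact tests do not take this into account.

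**Figure D1:**
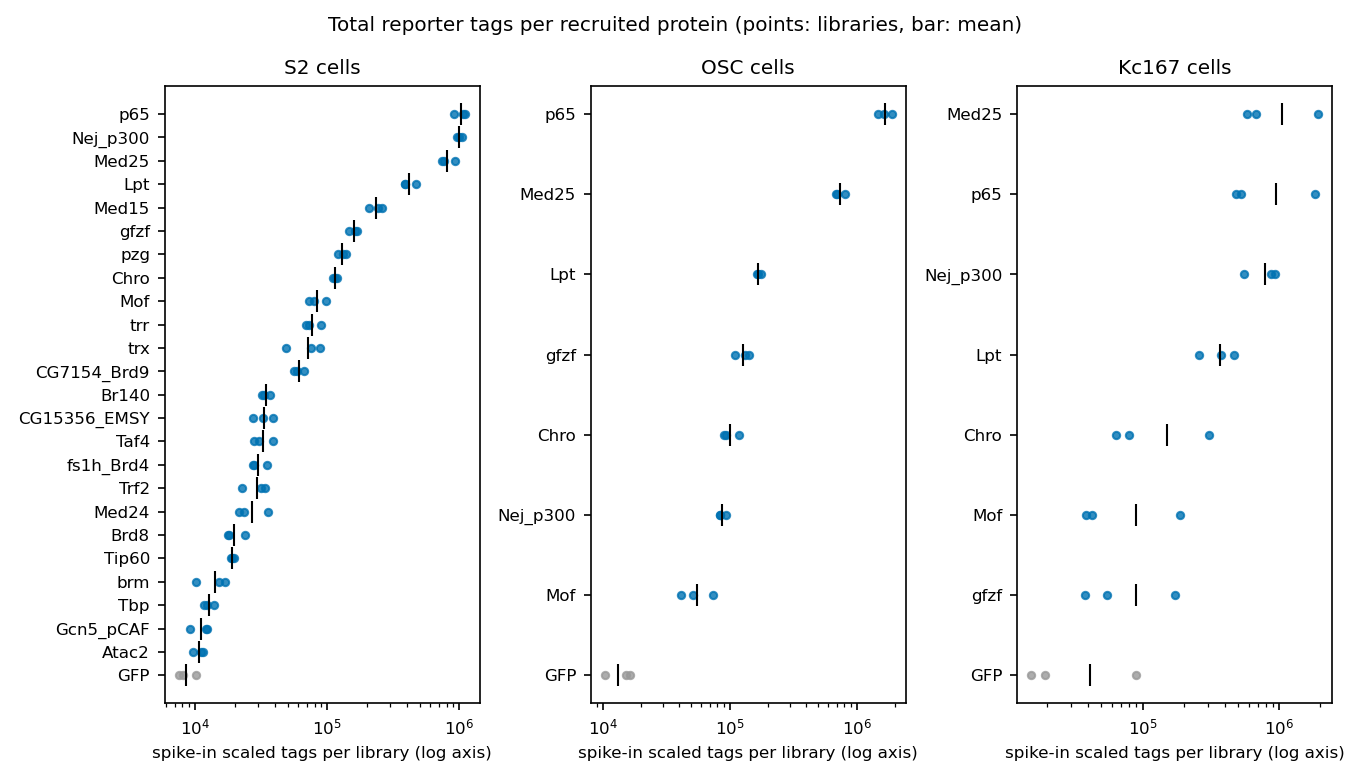
Spike-in scaled tags per library (log axis) for each recruited protein in S2, OSC and Kc167 cells, with points for libraries and bars for means. In S2 the p65, Nej_p300 and Med25 libraries lie 120-fold, 117-fold and 95.02-fold above GFP on average, while those of Gcn5_pCAF and Atac2 overlap GFP.

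Single promoters were then compared with GFP in S2 cells, over 9734 promoters. By TMM with all 6 GFP libraries the highest counts came from gfzf, with 6201 promoters higher and 1741 lower, pzg with 5782 and 1417, and Chro with 5605 and 1329. In this fit the strongest activators of the pool had lower counts above GFP and more promoters lower: Med25 4535 and 3529, Nej_p300 4439 and 3652, p65 4389 and 3530, Lpt 4279 and 2814, and Med15 4234 and 3499. With libraries thinned to at most 100000 tags, each of these activators had more promoters lower than higher. Among the chromatin readers and remodellers, Brd9 had 4247 higher and 3106 lower, fs1h_Brd4 3754 and 2446, Br140 3731 and 1504, and brm, the ATPase of the Brahma complex, 210 and 1. Of the methyltransferases trr had 3603 higher and 1152 lower and trx 2702 and 887. Of the general transcription factors Taf4 had 4199 higher and 894 lower, Trf2 3418 and 587, and Tbp 521 and 74. EMSY had 3681 and 758, Mediator subunit Med24 2326 and 170, Mof 2124 and 529, Tip60 1147 and 52, and Brd8 707 and 118. Atac2 raised 8 promoters and lowered 1, and Gcn5_pCAF raised 1 and lowered 1, by edgeR's test. At an unadjusted p under 0.05 there were 798 and 567 of the 9734 promoters, where unchanged promoters alone would give a share of about 0.05. DESeq2 called 28 and 1 higher, and for Atac2 it called more promoters lower than higher. Chosen after their values were seen, the promoters behind these smallest counts were 3L 3893264 to 3893396 on the minus strand, with 24 tags with Atac2 and 88 with GFP, 2L 7701533 to 7701665 on the minus strand, with 246 tags with Gcn5_pCAF and 143 with GFP, 3L 4242674 to 4242806 on the plus strand, with 21 and 105, and, for brm, 3R 25040213 to 25040345 on the plus strand, with 4 and 25.

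Measured against the spike-ins, with GFP replicates 1 to 3 alone, few promoters were called lower for most proteins. Decreases could be missed. In simulated counts for Chro against all 6 GFP libraries, 32% of the 4-fold and 4% of the 2-fold decreases were recovered. On the spike-in scale the typical promoter rose with p65 by a log2 of 6.01, where TMM placed it at 0.74, and with Med25 by 6.16 against 1.01. Promoters higher and lower numbered 8181 and 0 for p65, 7991 and 1 for Med25, 7908 and 4 for Nej_p300, 8766 and 1 for Lpt, 8890 and 2 for gfzf, 8680 and 1 for Chro, 8905 and 1 for pzg, and 6193 and 1 for Mof. The largest counts lower with the spike-ins were 452 for fs1h_Brd4, beside 3240 higher, and 190 for Brd9, beside 4577. For Med15 they were 5851 and 8, Br140 3880 and 12, EMSY 4651 and 26, trr 8368 and 1, trx 6513 and 0, Taf4 5819 and 9, Trf2 5179 and 2, Tip60 2187 and 48, Med24 3223 and 5, Brd8 2016 and 1, brm 339 and 0, Atac2 59 and 15, Gcn5_pCAF 42 and 0, and Tbp 12 and 0. The TMM counts therefore describe which promoters lay above or below the TMM average. With GFP replicates 1 to 3 alone the order turned: the TMM counts higher were 4472 for Med25, 4361 for Nej_p300 and 4249 for p65, above 3768 for Med15, 3751 for pzg, 3614 for Lpt, 3508 for gfzf and 3451 for Chro. In that setting Br140 had 2349, fs1h_Brd4 2187, EMSY 2167, trr 1828, trx 1655, Taf4 1049, Med24 963, Mof 780, Trf2 521, Brd8 47 and Tbp 7. Without replicate 2 of every protein the count was 7133 for trr, 6388 for Med24, 4668 for brm, 4171 for trx, 3739 for Tbp, 3055 for Tip60, 583 for Mof and 3 for Brd8. Without replicate 3 it was 1555 for Trf2, 1465 for Med24, 678 for Tip60, 167 for Brd8, 37 for brm and 13 for Tbp. Leaving out GFP replicate 3, 4, 5 or 6 gave 330, 120, 116 and 92 for brm and 1038, 289, 296 and 203 for Tbp. Atac2 had 0 to 13 with 1 replicate left out and 78 with GFP replicates 1 to 3 alone.

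The next question, given by the title of the series, was whether cofactors prefer classes of core promoters. The separate enhancer libraries split the promoters into 4446 zfh1-preferring and 2171 ssp3-preferring ones, of which 3328 and 2145 could be tested in S2. The zfh1 enhancer belongs to a developmental regulator and the ssp3 enhancer acts on housekeeping promoters. Med25 raised 3326 of the 3328 zfh1-preferring promoters and lowered none, with a median log2 of 4.43. Of the ssp3-preferring ones it raised 72 and lowered 1626, with a median of -3.35. Nej_p300 raised 3326 and lowered none, against 41 raised and 1690 lowered, p65 3307 and none against 51 and 1645, Med15 3286 and none against 24 and 1660, and Lpt 3166 and none against 97 and 1379. Brd9, fs1h_Brd4 and Br140 raised 3127, 2836 and 2661 zfh1-preferring promoters and lowered 1495, 1285 and 880 ssp3-preferring ones, the latter with medians of -2.54, -1.80 and -0.79. gfzf raised 2861 zfh1-preferring promoters and lowered 3, while it raised 881 and lowered 854 ssp3-preferring ones. Chro raised members of both classes: 1815 zfh1-preferring promoters against 5 lowered, and 1103 ssp3-preferring ones against 664 lowered. Mof raised 124 and lowered 137 zfh1-preferring promoters, and raised 861 and lowered 229 ssp3-preferring ones. EMSY raised 391 and lowered 11 of the former and raised 1163 and lowered 403 of the latter. Median log2 values were 1.76 and 0.94 for Chro, 2.62 and 0.11 for gfzf, -0.53 and 0.77 for Mof, and 0.71 and 1.31 for EMSY, in the zfh1- and the ssp3-preferring class.

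Against the remaining promoters, camera (limma) called the zfh1-preferring class up and the ssp3-preferring class down with Med25, with adjusted p = 3.6e-101 and 1.3e-49; with an estimated correlation these were adjusted p = 3.8e-04 and 0.0022. For p65 the latter were adjusted p = 2.8e-04 and 0.0022, and for Lpt 0.0012 and 0.0022. The class calls for Mof, down at zfh1-preferring and up at ssp3-preferring promoters, were lost with an estimated correlation, at adjusted p = 0.21 and 0.31, as were those for EMSY, at adjusted p = 0.51 and 0.58. Chro had no call at zfh1-preferring promoters (camera adjusted p = 0.69, with a median below and a mean above the other promoters), and its call at ssp3-preferring ones had adjusted p = 0.58 with an estimated correlation. gfzf kept its call at ssp3-preferring promoters (adjusted p = 0.035) and lost that at zfh1-preferring ones (adjusted p = 0.28). With the many promoters that had no GFP tag set to their bound, the zfh1-preferring medians were 4.23 for Med25, 4.37 for Nej_p300, 4.15 for p65, 3.51 for Lpt, 2.43 for gfzf and 1.55 for Chro. Over the 246 class tests camera made 132 calls, of which 77 were lost with an estimated correlation, and fry made 187.

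With the spike-in scale, the summed tags of the zfh1-preferring class rose 704-fold over GFP with p65 and those of the ssp3-preferring class 4.41-fold. The corresponding folds were 659 and 3.33 for Nej_p300, 485 and 3.44 for Med25, 259 and 4.78 for Lpt, 26.0 and 4.43 for gfzf, 13.9 and 6.23 for Chro, and 6.64 and 8.996 for Mof (exact permutation p = 0.1 for each, n = 3 against 3). The class totals at ssp3-preferring promoters with Brd9 and fs1h_Brd4 were 0.792-fold and 0.554-fold of GFP. The zfh1-preferring class held 14.4% ± 5.04 of all tags with GFP, 80.6% ± 0.298 with p65 and 14.3% ± 0.757 with Chro, and the ssp3-preferring class 54.5% ± 4.42 with GFP, 1.99% ± 0.0582 with p65 and 50.3% ± 0.392 with Mof (SD, n = 3, for GFP replicates 1 to 3). GFP replicates 4 to 6, which have no spike-in factor, held 6.46%, 7.79% and 7.14% at the zfh1-preferring class, below the share with Chro.

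**Figure D2:**
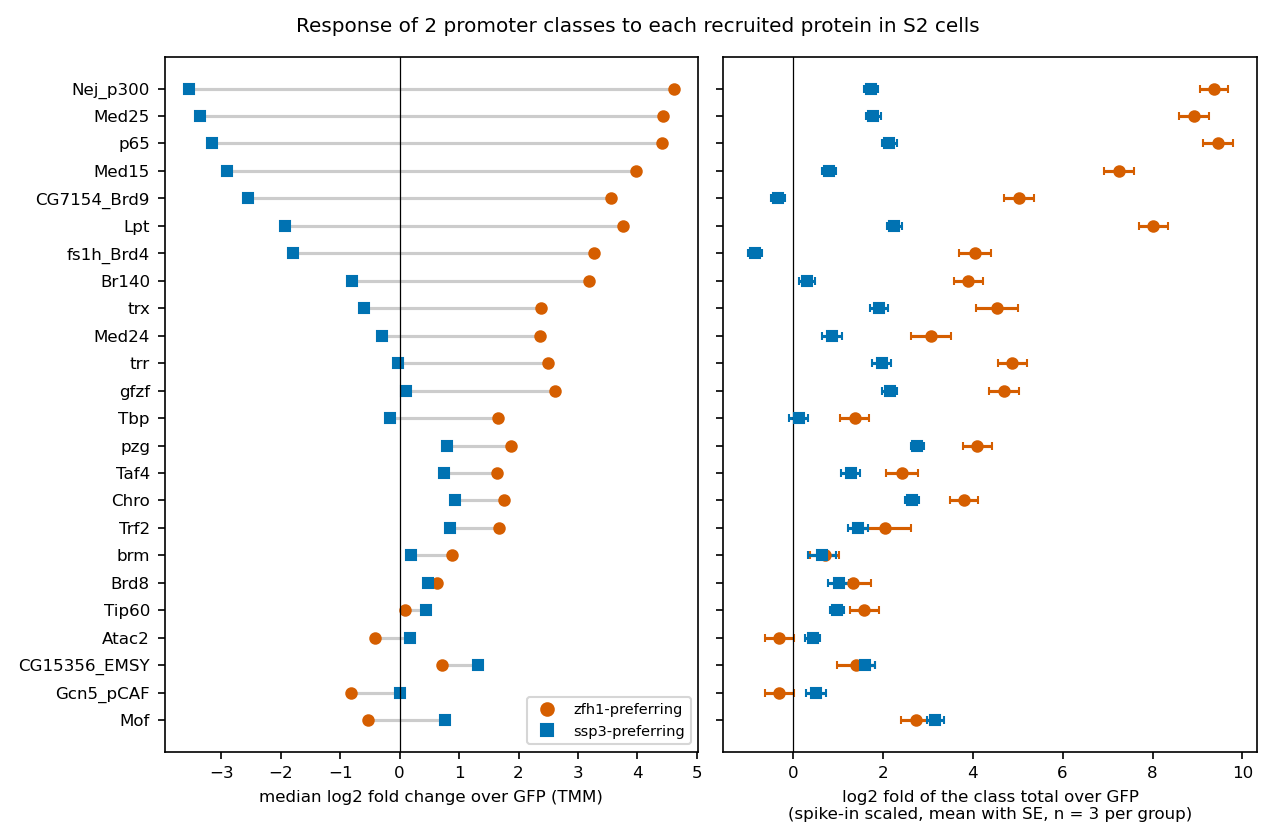
Left, the median log2 fold change over GFP (TMM) of the zfh1-preferring (circles) and the ssp3-preferring (squares) promoters for each protein in S2; right, the log2 fold of the class total over GFP on the spike-in scale, with SE. Nej_p300, Med25 and p65 part the classes the most, from -3.55, -3.35 and -3.15 to 4.61, 4.43 and 4.41, while on the spike-in scale both classes lie above 0 for these proteins.

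Med25 and Chro were compared with each other, in the fit of all S2 libraries. Of the 3328 zfh1-preferring promoters 3166 were higher with Med25 and 15 higher with Chro, with a median log2 of 2.52. Of the 2145 ssp3-preferring promoters none was higher with Med25 and 2134 were higher with Chro, with a median of -3.71. The class medians thus lay 6.22 apart on the log2 scale. Per library, the difference between the classes was 5.66 ± 0.059 (SE, n = 3 each) larger with Med25 than with Chro. With an estimated correlation the shifts had camera adjusted p = 2.2e-08 and 0.0022. Divergent pairs went with Chro, 2831 higher with it and 514 with Med25 (adjusted p = 0.011 with an estimated correlation). Heterochromatic and unplaced promoters went the other way, 239 higher with Med25 and 65 with Chro, and that call was lost with an estimated correlation (adjusted p = 0.078). In all, 3680 promoters were higher with Med25 and 5489 with Chro by edgeR's test. With the 2 groups fitted alone these were 4117 and 5124, and the class medians lay 6.24 apart. The larger side turned in other settings, to 4816 and 3171 with the spike-ins, 4753 and 3450 with DESeq2 and 15456 and 15241 without a filter.

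The promoter most raised with Med25 over Chro lay on chromosome X, 21300231 to 21300363 on the minus strand, with 656 tags against 0, at least 41.2-fold higher. Next was 2R, 9010579 to 9010711 on the plus strand, with 534 tags against 0, at least 32.2-fold higher. Both were zfh1-preferring. In the other direction 3R, 25045832 to 25045964 on the plus strand, an ssp3-preferring promoter, had 1 tag with Med25 and 500 with Chro, a ratio of 2620 in favour of Chro with an interval of 468 to 103700. The promoter on 2L, 15297779 to 15297911 on the plus strand, in neither class, had no tag with Med25 and 221 with Chro, at least 378-fold lower. CPM at 3R 25045832 were 582 ± 103 with Chro and 0.189 ± 0.328 with Med25 (SD, n = 3). The adjusted p of edgeR's test was 1.3e-16 or lower for these 4.

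Nej_p300 and gfzf differed in the same 2 classes. Of the zfh1-preferring promoters 3002 were higher with Nej_p300 and 63 with gfzf, with a median log2 of 2.04, and of the ssp3-preferring ones none was higher with Nej_p300 and 2127 with gfzf, with a median of -3.22. With an estimated correlation, the adjusted p was 1.2e-07 and 0.0075. The classes differed by 4.43 ± 0.13 more with Nej_p300 than with gfzf (SE, n = 3 each). In all 3461 promoters were higher with Nej_p300 and 5504 with gfzf, which turned to 5049 and 2793 with the spike-ins and 4635 and 3474 with DESeq2. The largest increase with Nej_p300 was at 3L, 17877408 to 17877540 on the minus strand, with a log2 of 4.98 ± 0.44 and 1423 tags against 8. The promoter on 3R at 21209358 to 21209490, plus strand, followed with 4.95 ± 0.47 and 918 tags against 5. In the opposite direction, 3L 2587398 to 2587530 on the plus strand had 3 tags with Nej_p300 and 657 with gfzf, a ratio of 1210 with an interval of 412 to 5880. The promoter on X at 6527832 to 6527964, plus strand, had none and 211, at least 366-fold lower with Nej_p300.

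Lpt and Mof, which act in complexes that modify different histones, parted the classes furthest of the 3 direct comparisons. With Lpt 3301 zfh1-preferring promoters were higher and none lower than with Mof, with a median log2 of 4.53, or 3.82 with bounds for promoters that had no tag. At ssp3-preferring promoters 27 were higher with Lpt and 1958 with Mof, with a median of -2.53. The class shifts had adjusted p = 3.6e-06 and 3.8e-04 with an estimated correlation, and divergent pairs, 658 higher with Lpt and 2467 with Mof, adjusted p = 0.0033. Over all promoters 4318 were higher with Lpt and 4469 with Mof, which turned to 4765 and 2875 with the spike-ins, 5057 and 1905 with DESeq2, 4513 and 4132 with GFP replicates 1 to 3, 4891 and 2647 with the groups fitted alone, 20707 and 212 without a filter, 4907 and 481 without replicate 2 and 4351 and 3971 without replicate 3. The promoters on 3L at 11807696 to 11807828, minus strand, and on 3R at 19998286 to 19998418, plus strand, had 1848 and 1681 tags with Lpt and none with Mof, at least 104-fold and 94.6-fold higher. The promoter on 2R at 8644922 to 8645054, minus strand, had 1 tag with Lpt and 35 with Mof, a ratio of 205 with an interval of 34.4 to 8316. With every library thinned to at most 100000 tags, a setting chosen after the data were seen, the 3 comparisons had 1977, 1321 and 2865 promoters higher, and without a filter they had 15456, 12558 and 20707.

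Proteins were grouped by how alike their promoter responses were. Med25 and Nej_p300 had a correlation of log2 fold changes across promoters of 0.992, Nej_p300 and p65 of 0.983, Lpt and p65 of 0.970, and Chro and pzg of 0.982. Chro and gfzf gave 0.923, while Chro and Med25 gave 0.483. Mof had -0.185 with Nej_p300 and -0.171 with Med25, and 0.661 with Tip60, 0.584 with EMSY and 0.576 with Brd8, where unchanged groups gave 0.658, 0.542 and 0.474 and split GFP libraries 0.143, 0.251 and 0.140. The covariances of these 3 pairs were 2.26, 2.91 and 2.24 against 0.946, 0.931 and 0.900 for unchanged groups. Gcn5_pCAF, at -0.152 and -0.154, and Atac2, at -0.0886 and -0.0806, were also below 0 with Nej_p300 and Med25. Because all share the GFP libraries, unchanged groups also correlate: simulated ones gave 0.329 to 0.946 with a median of 0.581, against an observed median of 0.466 over 276 pairs. Covariances were therefore compared, with 16.2 for Med25 and Nej_p300 where unchanged groups gave 0.994, 6.15 for Chro and pzg against 0.958, and -1.62 for Mof and Nej_p300 against 0.950. When the GFP libraries were split between the proteins of a pair, the correlations were 0.806 for Med25 and Nej_p300, 0.605 for Chro and pzg and -0.228 for Mof and Nej_p300, with a median of 0.158. Promoters are not independent replicates, so no p is given.

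**Figure D3:**
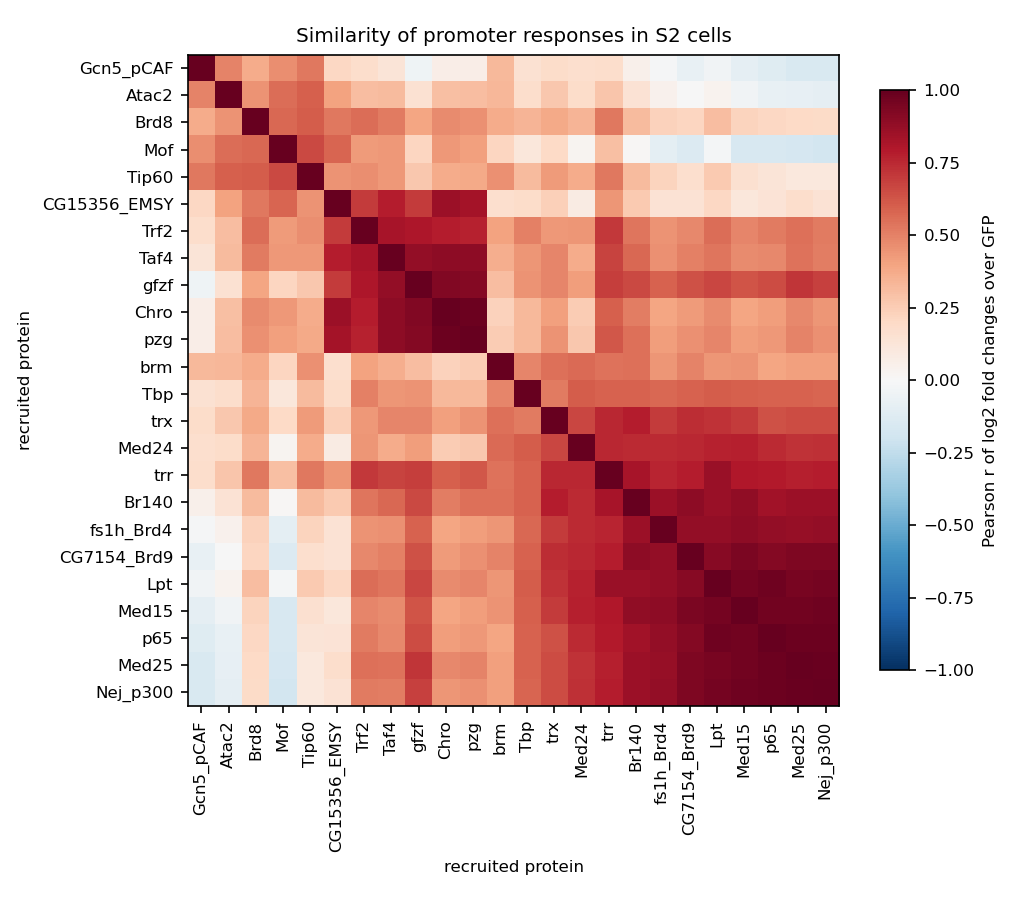
Pearson correlation of log2 fold changes over GFP across 9734 promoters for each pair of proteins in S2, with proteins ordered by clustering. One block joins Nej_p300, Med25, p65, Med15 and Lpt, another Chro, pzg, gfzf and Taf4, and Mof and Nej_p300 lie below 0 at -0.185.

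The enhancer screens asked how the same promoters respond to 2 enhancers of different kinds. The ssp3 enhancer has 1 library, so no test is given. Of 8002 promoters with at least 100 tags 4446 had at least 4-fold higher CPM, the tags scaled to a common library total, with the zfh1 enhancer and 2171 with the ssp3 enhancer, and 1385 lay between. The 100 tags were raw tags summed over the zfh1 libraries, with 2259292 and 2820163 tags, and the ssp3 library, with 732521. A promoter driven by the zfh1 enhancer therefore passed at a lower CPM. The sizes of the 2 classes do not show which preference is more common. The promoter on 3R at 14061850 to 14061982 had 1437 and 1397 tags in the zfh1 libraries and none with ssp3. In contrast 3L 2587398 to 2587530, the promoter that gfzf raised the most over Nej_p300, had 5 and 1 tags with zfh1 and 977 with ssp3, a log2 ratio of -9.66. The promoter on 3R at 25045832, highest with Chro over Med25, was also among the 5 lowest ratios. Across promoters the zfh1 over ssp3 ratio correlated with the log2 fold change of Med25 over Chro at r = 0.946, of Nej_p300 over gfzf at 0.926 and of Lpt over Mof at 0.914, of 81 such correlations computed. For fold changes over GFP it was 0.817 for Med25, 0.845 for Nej_p300 and 0.790 for Lpt. Chro had -0.035, gfzf 0.256 and Mof -0.483. Over the 9734 promoters tested in S2, the median ratio was -2.08. Among these it was -4.48 for divergent pairs, below all 10000 random lists matched on expression, 2.42 for heterochromatic and unplaced promoters, at percentile 99.8, -2.46 on chromosome X, at percentile 1.2, and -4.53 on chromosome 4, at percentile 13.6. The lists draw promoters within the same libraries, so the percentiles hold no spread between libraries and are descriptions only. The log2 CPM of both zfh1 libraries, not their ratios, correlated with each other at 0.985. The spike-in scaled total was 38.3-fold over no enhancer with zfh1 and 5.10-fold with ssp3.

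**Figure D4:**
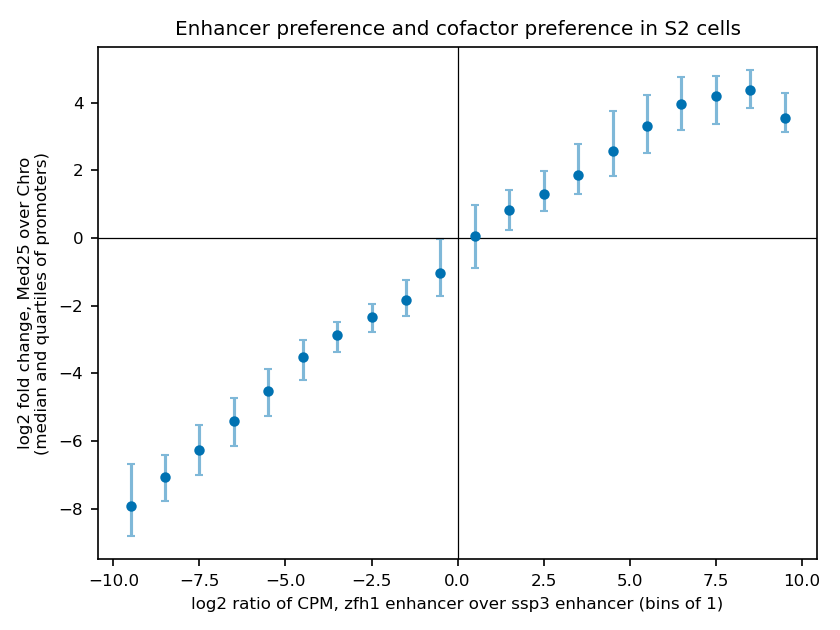
Median and quartiles of the log2 fold change of Med25 over Chro (vertical) in bins of 1 of the log2 ratio of CPM with the zfh1 over the ssp3 enhancer (horizontal). The medians run from -7.92 in the lowest bin to 4.37 in the second highest, along an overall r of 0.946.

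In OSC cells, over 28010 promoters, p65 had 13384 promoters higher than GFP and 2048 lower, Med25 13224 and 2284, Lpt 10748 and 162, gfzf 10743 and 863, Nej_p300 9783 and 35, Chro 7902 and 541, and Mof 2732 and 11. The median fitted log2 was 4.28 for p65, 4.24 for Med25, 4.16 for Lpt, 5.47 for gfzf, 4.19 for Nej_p300, 4.25 for Chro and 2.56 for Mof. A promoter called higher could thus lie below the fitted median. Many promoters had no GFP tag, and their fitted values are not measured folds. In the comparison with Med25 these included 1418 of the 4402 zfh1-preferring ones. With DESeq2 and its own scaling the medians were 3.06 for p65, 3.18 for Med25, 1.11 for Lpt, 2.79 for gfzf, 0.859 for Nej_p300, 1.86 for Chro and 0 for Mof. At zfh1-preferring promoters p65 raised 4380 of 4402 and lowered none, Med25 4362 and 1, Lpt 4195 and none and Nej_p300 4154 and none, while Chro raised 734, gfzf 1325 and Mof 475. At ssp3-preferring promoters Med25 raised 189 and lowered 1036, p65 216 and 994, Chro 940 and 318, gfzf 694 and 491, and Mof 794 and 8. With bounds for promoters without a GFP tag, the zfh1-preferring medians were 4.21 for Med25, 4.14 for p65, 4.04 for Nej_p300, 4.00 for Lpt, 1.37 for Mof, 1.36 for gfzf and 0.79 for Chro. The camera calls at zfh1-preferring promoters held with an estimated correlation for Lpt (adjusted p = 0.035) and Nej_p300 (0.029) and were lost for Med25 (adjusted p = 0.11) and p65 (0.088). The fitted median of Mof at ssp3-preferring promoters lay below that of the other promoters while camera called the class up, a call lost with an estimated correlation (adjusted p = 0.47). The same held for the direction of gfzf at zfh1-preferring promoters, which camera did not call (adjusted p = 0.076, and 0.92 with an estimated correlation). On the spike-in scale 26204 promoters were higher and 1 lower with p65, 26125 and 4 with gfzf, 22623 and 20 with Med25, 21882 and 2 with Chro, 16605 and 8 with Lpt, 11111 and 24 with Nej_p300, and 8815 and 0 with Mof. With GFP replicates 1 and 2 kept apart, TMM gave 15334 higher for Chro, 19715 for gfzf and 6201 for Mof. DESeq2 gave 4149 higher for Chro, 8298 for gfzf, 6457 for Lpt, 6026 for Nej_p300, 14460 for Med25 and 14227 for p65. The OSC counts rest on 2 GFP samples: by TMM without replicate 3 there were 549 higher and 114 lower for Chro, 448 and 0 for Mof, 7471 and 1301 for p65, 8052 and 1406 for Med25, 4807 and 39 for Lpt and 5013 and 8 for Nej_p300. Without replicate 1 they were 1714 and 984 for Chro, 362 and 151 for Mof, 6380 and 817 for Lpt and 4945 and 672 for Nej_p300, and without replicate 2 Mof had 1568 and 25. The calls for gfzf turned to mostly lower without replicate 3 (52 and 115), without replicate 1 (849 and 1107) and without a filter (1057 and 1133), as did those for Mof with DESeq2 (264 and 618).

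In Kc167 cells, over 15614 promoters, Med25 raised all 4196 zfh1-preferring promoters, p65 4195, Nej_p300 4183 and Lpt 3105, and none of these proteins lowered one. Chro raised 107 and lowered 250, gfzf raised 57 and Mof raised 98. At ssp3-preferring promoters Med25 raised 200 and lowered 1250, p65 174 and 892, and Chro 654 and 648. Median log2 values at zfh1-preferring promoters were 5.95 for Med25, 5.82 for p65, 5.08 for Nej_p300 and 3.40 for Lpt, or 5.51, 5.19, 4.64 and 2.70 with bounds, and with an estimated correlation the adjusted p was 0.018, 0.0088, 0.0095 and 0.027. Over all promoters Med25 had 7778 higher and 2921 lower, p65 7550 and 1828, Nej_p300 7281 and 415, Lpt 4576 and 49, Chro 4007 and 1507, gfzf 925 and 30, and Mof 800 and 33. With the spike-ins these were 8704 and 2, 8223 and 0, 9141 and 0, 7938 and 0, 6649 and 8, 1408 and 0, and 127 and 0. By TMM without replicate 1, gfzf had 104 higher and 6 lower and Mof 111 and 26, without replicate 2 gfzf had 1566 and 1 and Mof 517 and 3, and without replicate 3 Chro had 2488 and 830, gfzf 153 and 3 and Mof 180 and 0. With DESeq2 Mof had 280 higher and 295 lower.

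Differences between lines were tested over 32281 promoters. By TMM, with the lines fitted together, the effect of Nej_p300 differed at 1642 promoters between OSC and S2 and at 2186 between Kc167 and S2, the highest counts of the 7 proteins. With the compared groups fitted alone, Lpt had more between Kc167 and S2, at 1529 against 807. Of the 2168 ssp3-preferring promoters 899 had a higher Nej_p300 effect in OSC than in S2 and 1 a lower one, and 120 of the 4439 zfh1-preferring promoters had a lower effect and none a higher one. With the spike-in factors and S2 GFP replicates 1 to 3, a setting added after the data were seen, the direction turned: 837 promoters differed, all lower in OSC, of which 581 were zfh1-preferring and 53 ssp3-preferring. The Nej_p300 effect in Kc167 was higher than in S2 at 1070 ssp3-preferring promoters by TMM, while with the spike-in factors edgeR called none of all promoters, with 1578 at an unadjusted p under 0.05. The log2 fold of the total of the ssp3-preferring class with Nej_p300 over GFP was 1.74 ± 0.16 in S2, 0.22 ± 0.19 in OSC and 2.03 ± 0.78 in Kc167 (SE; exact permutation p = 0.1, 0.2 and 0.1). For gfzf 1290 promoters differed between Kc167 and S2 by TMM, 1203 of them higher in Kc167, but with the spike-in factors 309 differed, all lower in Kc167. For Lpt 1384 differed, 740 of them ssp3-preferring promoters with a higher effect in Kc167, and none with the spike-in factors (2172 at an unadjusted p under 0.05). The spike-in fit has no replicate term. In Kc167, replicate 2 had the highest spike-in scaled total with GFP, Med25, p65, Chro, Mof and gfzf. Low or empty spike-in counts there do not show that the effects are equal. By TMM the counts for p65 were 89 in OSC and 485 in Kc167, for Chro 32 and 238, for Med25 15 and 40, and for gfzf in OSC 17. With the compared groups fitted alone, p65 had 6 in Kc167, Med25 2 and gfzf 797, while Chro had more, at 534. The effect of Mof differed at no promoter in OSC by edgeR (2603 at an unadjusted p under 0.05) and at 1 in Kc167, 2L 16719871 to 16720003 on the plus strand. These Mof counts moved widely: in OSC to 59 with S2 GFP replicates 1 to 3, of which 57 were zfh1-preferring and higher in OSC, 73 with the OSC GFP libraries apart, 268 without replicate 1 and 8 without replicate 2, and in Kc167 to 1077 without replicate 2 and 92 with the spike-in factors. The Lpt effect differed in OSC at 4 promoters. It was higher at X 6697571 to 6697703 and 3L 11203754 to 11203886, both on the minus strand, and lower at 2L 11004767 to 11004899 and 3L 21567596 to 21567728, both on the plus strand. X 6697571, with 239 tags with Lpt and 0 with GFP in OSC, was also called higher with Med25 and p65. Likewise 2L 11004767 was called lower with gfzf, and 2L 16719871 lower with Med25 in Kc167. Such calls share their GFP libraries and are not independent. These 5 promoters were named after their values were seen. By TMM with S2 GFP replicates 1 to 3 alone, 796 of 805 Nej_p300 differences were higher in OSC and 1073 of 1078 higher in Kc167. In that setting edgeR called none for Chro, gfzf and Lpt in OSC, with 869, 852 and 703 at an unadjusted p under 0.05, while Chro in Kc167 had 3, Med25 4 in OSC and 2 in Kc167, and p65 19 and 72. Unchanged promoters alone would give a share of about 0.05 of the 32281. The counts of 869, 852 and 703, and the 1578 for Nej_p300 in Kc167, lie under that share. With a replicate left out the Chro count in Kc167 lay between 8 and 176, and its larger side turned to lower in Kc167 without replicate 1 (8 of 8) and replicate 3 (168 of 176).

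Cross-line correlations of the log2 fold changes of the same protein had medians of 0.708 between S2 and OSC, 0.711 between S2 and Kc167 and 0.571 between OSC and Kc167, against 0.386, 0.309 and 0.231 for different proteins, over 147 pairs. They were highest for Med25, at 0.810, 0.886 and 0.768, and lowest for Mof, at 0.159, 0.341 and 0.240. A protein was its own best match in 3, 4 and 2 of 7 cases.

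Named constructs allowed a look at defined core promoters. DSCP, a synthetic core promoter assembled from developmental elements, rose in S2 with p65 by a log2 of 5.50 ± 0.37, with Lpt by 5.06 ± 0.38, with Nej_p300 by 4.90 ± 0.39, with Med15 by 4.53 ± 0.40 and with Med25 by 4.26 ± 0.40 (SE, n = 3 against 6 GFP libraries with 0 to 3 tags each). It rose less with gfzf, by 1.60 ± 0.53, and with Chro, by 1.25 ± 0.55 (edgeR adjusted p = 0.036), and with Mof its value was 0.06 ± 0.69 (adjusted p = 0.98). These values are relative to the TMM average, and the order differed on the spike-in scale. There DSCP had a mean of 627 scaled tags with p65, 428 with Nej_p300, 249 with Med25, 235 with Lpt, 98.1 with Med15, 7.28 with gfzf, 4.56 with Chro and 2.04 with Mof, against 0.359 over GFP replicates 1 to 3, which had few tags of it. In OSC it rose with Lpt by 4.93 ± 0.69, with Nej_p300 by 4.66 ± 0.70, with p65 by 4.60 ± 0.70 and with Med25 by 4.11 ± 0.71. The order differed there too on the spike-in scale, with 449 scaled tags with p65, 131 with Med25, 46.6 with Lpt and 20.8 with Nej_p300. In Kc167 DSCP rose with p65 by 6.43 ± 0.48, with Med25 by 5.33 ± 0.49, with Nej_p300 by 4.92 ± 0.49 and with Lpt by 3.76 ± 0.51.

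Mutant forms of the promoters of the segmentation genes ftz and gt were compared within libraries, since the 6 S2 GFP libraries together gave 2 tags at the ftz and 1 tag at the gt DPE mutant. The log2 ratio of tags of the DPE mutant over the TATA mutant was below 0 for both genes with all 4 proteins in S2. For gt it was -3.84 ± 0.11 with p65, -3.44 ± 0.40 with Med25, -3.98 ± 0.30 with Nej_p300 and -4.69 ± 0.11 with Lpt, and for ftz -0.55 ± 0.23, -0.56 ± 0.28, -0.999 ± 0.19 and -2.79 ± 0.27 (SD, n = 3). Lpt lay below each of the other proteins with no overlap for both genes, by 2.24 ± 0.20 (SE) against p65 for ftz (exact permutation p = 0.1, the smallest possible, 12 pairs tested). The ratio also depends on how much of each mutant the pool held, which was not analysed here, so only differences between screens are informative.

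**Figure D5:**
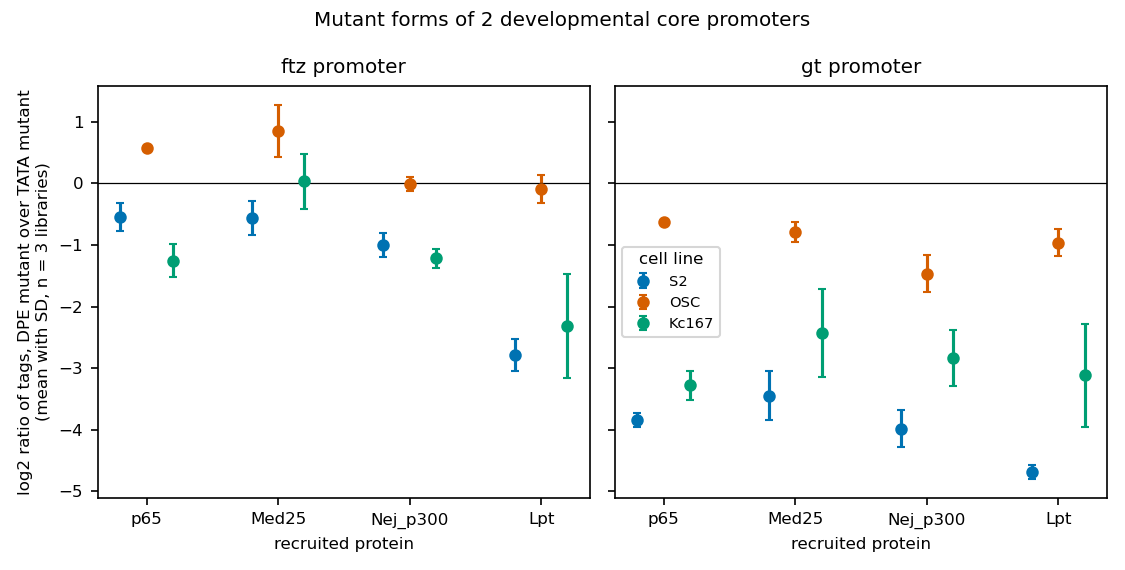
The log2 ratio of tags, DPE mutant over TATA mutant, of the ftz and gt promoters for 4 recruited proteins in S2, OSC and Kc167 cells, as means with SD over 3 libraries. Lpt in S2 has the lowest ratios, at -2.79 for ftz and -4.69 for gt.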

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

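The tests of Nej_p300 against p65, the test with GFP replicates 1 to 3 and all split counts within S2 and within Kc167 were chosen after the results were seen. The predictions for depth, for sparse promoters, for TMM scaling and for the split counts between Kc167 and S2 were set before. The thinning that the depth test uses was itself added after the data were seen.

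A difference between cell lines, by the interaction test, singled out 13 results. For OSC against S2 the effect differed at 1642 promoters for Nej_p300, 89 for p65, 32 for Chro, 17 for gfzf, 15 for Med25 and 4 for Lpt. For Kc167 against S2 it differed at 2186 promoters for Nej_p300, 1384 for Lpt, 1290 for gfzf, 485 for p65, 238 for Chro, 40 for Med25 and 1 for Mof. All were called by TMM with 6 S2 GFP libraries. With the compared groups fitted alone, Kc167 against S2 gave 6 for p65, 2 for Med25, 797 for gfzf and 807 for Nej_p300. In that fit Lpt had 1529, Chro 534 and Mof 4. With TMM and S2 GFP replicates 1 to 3 alone, Chro, gfzf and Lpt in OSC and Mof in Kc167 had 0, Med25 in OSC 4, Med25 in Kc167 2, Chro in Kc167 3, p65 in OSC 19 and p65 in Kc167 72. The others kept more: Nej_p300 805 in OSC and 1078 in Kc167, and gfzf 594 and Lpt 438 in Kc167. With those GFP libraries and the spike-in factors 10 of the 13 had 2 promoters or fewer, and Nej_p300 in OSC had 837, gfzf in Kc167 309 and Mof in Kc167 92, all lower than in S2. That fit has no replicate term, so low counts in Kc167 do not show that the effects are equal. Dixon's test, which needs at least 4 samples, could be made only for the 6 S2 GFP libraries and set none of them apart: of 5 measures the highest ratio was 0.527, below the critical value. It looks for 1 extreme library and cannot show a difference between replicates 1 to 3 and 4 to 6. An edgeR test of those sets alone called 30 of 9734 promoters higher and 23 lower in replicates 4 to 6.

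In the direct comparison in S2, zfh1-preferring promoters were mostly higher with Med25 and ssp3-preferring ones mostly higher with Chro, with class medians 6.22 apart, although against GFP Chro raised members of both classes. With their libraries thinned to 100000 tags the difference was 6.06 and among the promoters with the highest average expression it was 5.34, which argues against a difference in depth or noise at promoters with few tags as the whole cause. The recruited protein is the difference the design names, and a class preference of the proteins is a hypothesis that these tests leave open.

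The total activity of Nej_p300 against p65 was lower in OSC than in S2, with a log2 difference of -4.22 ± 0.15 (SE, 12 libraries), while in Kc167 the log2 of Nej_p300 over p65 was -0.005 ± 0.67. With raw totals, which do not use the spike-in factors, the OSC minus S2 difference was -2.38 ± 0.70. Its direction stayed without the factors, while its size shrank. The factors in OSC were 0.087 to 0.153 for Nej_p300 and 0.326 to 0.899 for p65. Raw totals also depend on library depth, so they cannot decide how much of the difference the factors make. With 1 library left out in turn the spike-in scaled difference lay between -4.31 and -4.12, which argues against a single library. The amount of Nej_p300 protein that was recruited in each line was not measured here, so a weaker recruitment and a weaker response of OSC promoters both stay open.

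Leaving out replicate 2 of every protein moved the S2 counts: the summed counts higher than GFP went from 75843 to 104223. With the spike-in factors the ratio was 0.96, but that fit holds GFP replicates 1 to 3 alone and so does not decide about TMM scaling. With TMM and GFP replicates 1 to 3 alone the ratio was 0.902, from 49332 to 44504, so the move may come from GFP replicates 4 to 6. GFP replicates 4 to 6 held 6.46%, 7.79% and 7.14% of their tags at zfh1-preferring promoters, against 10.3%, 12.9% and 20.01% in replicates 1 to 3. In the sample list, GFP replicates 4 to 6 stand in a block with Atac2, Br140, Gcn5_pCAF, Med24, Taf4, Tbp, Tip60, Trf2, brm and pzg. Replicates 1 to 3 stand in another with the remaining S2 proteins. The labels do not say whether these blocks are batches. On the spike-in scale all S2 proteins, of either block, were set against replicates 1 to 3. Why the libraries of replicates 4 to 6 differ was not tested.

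The groups were split in other ways, each pair fitted alone. Of 40 splits drawn of 3 libraries of a protein and the GFP libraries in S2, only the real one, 1 of them, gave as many promoters higher for 21 proteins. This argues against chance, at the smallest share that 40 splits allow and with no correction over the 24 proteins. Splits that mix the groups widen the spread within groups, so the gap to them does not measure an effect. The real count and the highest of the others were 3960 and 0 for Br140, 192 and 24 for Brd8, 48 and 15 for brm, 3322 and 86 for EMSY, 4699 and 0 for Brd9, 5397 and 2 for Chro, 3957 and 8 for fs1h_Brd4, 5691 and 600 for gfzf, 5389 and 0 for Lpt, 4862 and 0 for Med15, 1925 and 10 for Med24, 4676 and 190 for Med25, 1940 and 110 for Mof, 5526 and 0 for Nej_p300, 5444 and 0 for p65, 5643 and 320 for pzg, 3305 and 208 for Taf4, 620 and 65 for Tip60, 1506 and 60 for Trf2, 4011 and 89 for trr and 2546 and 103 for trx. Chance cannot be excluded for Atac2, where 2 of the splits gave as many (16 against up to 88), Gcn5_pCAF, where 6 of the splits gave as many (1 against up to 50) and Tbp, where 2 of the splits gave as many (34 against up to 232). With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Counting promoters higher and lower together, the real count and the highest other were 9241 and 0 for Med25 against Chro, 9068 and 0 for Nej_p300 against gfzf and 7538 and 0 for Lpt against Mof. In Kc167 against GFP these were 6110 and 0 for Chro, 230 and 3 for gfzf, 4516 and 0 for Lpt, 9829 and 0 for Med25, 947 and 3 for Mof, 8109 and 0 for Nej_p300 and 9983 and 0 for p65. For the differences between Kc167 and S2, over 40 splits, only the real one gave as many for Chro (534 against up to 38), gfzf (797 against up to 6), Lpt (1529 against up to 0) and Nej_p300 (807 against up to 0). This argues against chance for these proteins in this setting alone. Chance cannot be excluded for Med25, where 4 splits gave as many (2 against up to 29), Mof, where 14 splits gave as many (4 against up to 93) and p65, where 9 splits gave as many (6 against up to 1113). The splits do not show that a count holds in other settings: the Chro count in Kc167 was 3 with S2 GFP replicates 1 to 3 alone and 8 without replicate 1, and with the spike-in factors edgeR called none for Chro, Lpt and Nej_p300 (2980, 2172 and 1578 at an unadjusted p under 0.05). The 1578 lies under the share that unchanged promoters alone would give. The spike-in fit has no replicate term, so these empty counts do not show that the effects are equal. Splits that called several times the real count, the highest being 1113 for p65, point to some structure of these samples, and what sets those splits apart was not tested. OSC, with 2 GFP samples, has no such count.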

How the results depend on the processing

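Thinning, the OSC GFP libraries kept apart and the spike-in factors for differences between lines were tests chosen after the results were seen; the others were set before. The larger side of the calls, higher against lower, turned in several settings. With DESeq2 it turned for Med25 over Chro (4753 and 3450), Nej_p300 over gfzf (4635 and 3474), Lpt over Mof (5057 and 1905), Atac2 in S2 (28 and 41), Mof in OSC (264 and 618) and Mof in Kc167 (280 and 295). With the spike-in factors it turned for the 3 direct comparisons (4816 and 3171, 5049 and 2793, 4765 and 2875). With thinning it turned for Br140 (2187 and 2793), Brd9 (2866 and 3582), fs1h_Brd4 (2249 and 3112), Lpt (2479 and 3067), Med15 (2903 and 3636), Med25 (3342 and 3620), Nej_p300 (3272 and 3718), p65 (2802 and 3436) and trx (1540 and 2134). Without a filter it turned for Med25 over Chro (15456 and 15241), Lpt over Mof (20707 and 212) and gfzf in OSC (1057 and 1133), which also turned without replicate 1 (849 and 1107) and without replicate 3 (52 and 115). Lpt over Mof, nearly even at 4318 and 4469, turned too without replicate 2 (4907 and 481), without replicate 3 (4351 and 3971), with the replicate block (4518 and 4145), with GFP replicates 1 to 3 alone (4513 and 4132) and with these groups fitted alone (4891 and 2647). The calls for Gcn5_pCAF were too few for a larger side. Between lines, counting effects higher and lower than in S2, the larger side turned with the spike-in factors for Nej_p300 in OSC (0 and 837), gfzf in Kc167 (0 and 309), p65 in OSC (1 and 0) and in Kc167 (0 and 2) and Med25 in Kc167 (0 and 1). It turned with the OSC GFP libraries apart for Chro (38 and 16) and Med25 (31 and 8) in OSC, and with S2 GFP replicates 1 to 3 alone for Chro in Kc167 (1 and 2). Leaving out a replicate turned it in Kc167 for Chro without replicate 1 (0 and 8) or 3 (8 and 168), Med25 without replicate 3 (2 and 7) and Mof without replicate 2 (1077 and 0) or 3 (1 and 0). Counts of promoters higher than GFP, higher with the first protein, or differing between lines, that moved by over 1.5 times are given by setting; the cause was not tested unless stated.

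With DESeq2 the counts were in S2 Atac2 28, Brd8 1369, brm 67, Taf4 6501, Tbp 1811 and Trf2 5299; in OSC Chro 4149, Lpt 6457, Mof 264 and Nej_p300 6026; in Kc167 gfzf 507 and Mof 280. With the spike-in factors they were in S2 Atac2 59, Brd8 2016, brm 339, Chro 8680, Gcn5_pCAF 42, Lpt 8766, Med25 7991, Mof 6193, Nej_p300 7908, p65 8181, pzg 8905, Tbp 12, Tip60 2187, Trf2 5179, trr 8368 and trx 6513; in OSC Chro 21882, gfzf 26125, Lpt 16605, Med25 22623, Mof 8815 and p65 26204; in Kc167 Chro 6649, gfzf 1408, Lpt 7938 and Mof 127. Without a filter they were in S2 Atac2 0, Br140 10457, Brd8 46, brm 6402, Brd9 12899, Chro 22762, fs1h_Brd4 7845, Gcn5_pCAF 0, gfzf 37608, Lpt 17978, Med15 14812, Med24 8090, Med25 21808, Mof 613, Nej_p300 20310, p65 20184, pzg 29083, Tbp 869, Tip60 4870, trr 14516, trx 6399, Med25 over Chro 15456, Nej_p300 over gfzf 12558 and Lpt over Mof 20707; in OSC Chro 2199, gfzf 1057, Lpt 6688, Mof 454 and Nej_p300 5751; in Kc167 Chro 6482, Lpt 15385, Med25 18890, Nej_p300 15931 and p65 16001. With the replicate block they were in S2 Atac2 84, Br140 2353, Brd8 43, EMSY 2150, Chro 3420, fs1h_Brd4 2197, Gcn5_pCAF 19, gfzf 3492, Med24 974, Mof 776, pzg 3753, Taf4 1030, Tbp 8, Trf2 506, trr 1862 and trx 1656; in OSC Chro 15163, gfzf 19509 and Mof 6156. Not every pair of same-numbered libraries correlated above 0.1 (median r 0.011 in S2, 0.018 in OSC and 0.004 in Kc167; 56%, 60.9% and 41.7% of libraries were closest to their own number), so the numbers were not taken as pairs, although more libraries in S2 and OSC were closest to their own number than an even choice among 3 gives. The S2 block fit leaves out GFP replicates 4 to 6 and the OSC block fit keeps GFP replicates 1 and 2 apart, which by itself gave 15334 for Chro. With GFP replicates 1 to 3 alone they were in S2 Atac2 78, Br140 2349, Brd8 47, EMSY 2167, Chro 3451, fs1h_Brd4 2187, Gcn5_pCAF 7, gfzf 3508, Med24 963, Mof 780, pzg 3751, Taf4 1049, Tbp 7, Trf2 521, trr 1828 and trx 1655. With the compared groups fitted alone they were in S2 Atac2 16, Brd8 192, brm 48, Tbp 34, Tip60 620 and Trf2 1506. With libraries thinned to at most 100000 tags they were in S2 Atac2 23, Br140 2187, Brd8 329, brm 374, Chro 3365, fs1h_Brd4 2249, Gcn5_pCAF 0, gfzf 3400, Lpt 2479, Med24 1463, Mof 1410, p65 2802, pzg 3209, Taf4 2700, Tbp 207, Tip60 461, Trf2 2153, trr 1723, trx 1540, Med25 over Chro 1977, Nej_p300 over gfzf 1321 and Lpt over Mof 2865. With GFP replicates 4 to 6 alone they were in S2 Gcn5_pCAF 6 and Tbp 861. With OSC GFP replicates 1 and 2 apart they were in OSC Chro 15334, gfzf 19715 and Mof 6201; for OSC against S2 Chro 54, gfzf 149, Med25 39, Mof 73 and p65 40. Between lines, S2 GFP replicates 1 to 3 alone gave for OSC against S2 Chro 0, gfzf 0, Lpt 0, Med25 4, Mof 59, Nej_p300 805 and p65 19; for Kc167 against S2 Chro 3, gfzf 594, Lpt 438, Med25 2, Mof 0, Nej_p300 1078 and p65 72. With the spike-in factors and S2 GFP replicates 1 to 3 the differences between lines were for OSC against S2 Chro 0, gfzf 0, Lpt 0, Med25 1, Mof 1, Nej_p300 837 and p65 1; for Kc167 against S2 Chro 0, gfzf 309, Lpt 0, Med25 1, Mof 92, Nej_p300 0 and p65 2. The stricter filter gave for OSC against S2 gfzf 30.

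With each replicate left out in turn, the counts ranged in S2 Atac2 0 to 13, Brd8 3 to 748, brm 37 to 4668, Gcn5_pCAF 0 to 2, Med24 1465 to 6388, Mof 583 to 2037, Tbp 13 to 3739, Tip60 678 to 3055, Trf2 1555 to 4617, trr 3125 to 7133 and trx 2466 to 4171; in OSC Chro 549 to 9441, gfzf 52 to 14616, Lpt 4807 to 11955, Med25 8052 to 13693, Mof 362 to 1568, Nej_p300 4945 to 11486 and p65 7471 to 13948; in Kc167 Chro 2488 to 4441, gfzf 104 to 1566 and Mof 111 to 517; for OSC against S2 Chro 0 to 1, gfzf 0 to 0, Lpt 0 to 0, Med25 3 to 13, Mof 0 to 268, Nej_p300 832 to 1382 and p65 3 to 52; for Kc167 against S2 Chro 8 to 176, gfzf 420 to 987, Lpt 622 to 2169, Med25 0 to 103, Mof 0 to 1077 and p65 88 to 907. In OSC, leaving out replicate 1 or 3 leaves a lone GFP sample, assumed to vary like the other groups. With the estimated correlation 55 of 246 class tests were called in place of 132, the median similarity was 0.158 with split GFP libraries in place of 0.466, and the enhancer correlation was 0.951 with edgeR's ratio and 0.943 to 0.946 without a zfh1 library, in place of 0.946. The fold threshold moved no count of promoters higher by over 1.5 times, but moved 6 counts of promoters lower. In addition, the stricter filter removed no S2 promoter and so tests nothing there. The alternative on motif mismatches was not run, since no sequences are given. The shallow GFP libraries limit which decreases could be seen, and OSC rests on 2 GFP samples.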

Other observations

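The observations here were chosen after the results were seen.

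The ratio of DPE mutant over TATA mutant tags was also measured in the other cell lines. For ftz the log2 ratio was -0.55 ± 0.23 with p65 in S2, 0.58 ± 0.05 in OSC and -1.26 ± 0.27 in Kc167, and with Lpt -2.79 ± 0.27, -0.09 ± 0.23 and -2.32 ± 0.84 (SD, n = 3). For gt with p65 it was -3.84 ± 0.11, -0.62 ± 0.02 and -3.28 ± 0.23, and with Lpt -4.69 ± 0.11, -0.96 ± 0.22 and -3.12 ± 0.84. The difference between lines was not tested, and the share of each mutant in the transfected pools was not analysed here.

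Lpt and trr, which are parts of the same complex, had a correlation of log2 fold changes of 0.860, close to the 0.850 that unchanged groups gave against the same GFP libraries, and a covariance of 5.05 where unchanged groups gave 0.970. With the GFP libraries split between them the correlation was 0.451. Chromosome X and chromosome 4 had no camera call in S2, and in OSC chromosome 4 was down in 3 of 7 comparisons, none of which held with an estimated correlation.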
